A study of Mus musculus with 12 samples.

How the data were processed

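The samples were 12 RNA-seq libraries of mouse sciatic nerve, 6 from controls with floxed Bap1 and 6 from animals that also carried a Cre transgene driven by the Mpz promoter. Per the labels' protocols, total RNA was selected for polyadenylated RNA and sequenced in pairs on an Illumina HiSeq. The count values are whole numbers of reads per Ensembl gene as the authors deposited them, with no normalization. Per the submitters' processing notes, CASAVA 1.9 and DESeq2 were used, STAR is named for 1 sample, and the builds are mm10 and GRCm38. The counter, the annotation release, the strand setting and the tool versions other than that of CASAVA were not given in the sources used here. The authors' deposited table holds log2 fold changes and their standard errors from DESeq2, per the file headers. It also holds the adjusted p-value of each gene, per the file headers, and lists only genes with an adjusted p-value of at most 0.0498. Its direction and design formula were not given in the sources used here, and 16 of its names are blank and 9 read as dates.

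Groups were taken from the genotype labels. Replicate numbers follow the order of deposit and only name libraries. The table held 43432 genes, of which 97.77% had a symbol, and genes without a symbol took at most 0.144% of a library's counts. Coordinates and exon overlaps came from a GRCm38 gene annotation. Totals ranged from 21461414 to 39554458 counts. No libraries of a group agreed within sampling noise.

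Counts were filtered with filterByExpr by group, leaving 16997 genes, scaled by TMM and tested two-sided with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors were derived from the fold change and the F statistic. Levels are CPM with TMM-scaled library sizes, and log2 CPM used a prior count of 2. The Bap1 group means were also compared by an exact permutation test. The 33 fixed gene lists were ranked against other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Tables were handled with the R package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

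Genes were named by a rule set before the data were examined. It took Bap1, and the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 1, no overlap between the groups and a symbol that is not a clone or predicted name. It also took up to 4 measured members of each fixed list with the smallest adjusted p and, in a list with no call, also the member with the highest mean CPM. Members named beyond that rule were chosen after their values were seen, among them Mpz, Drp2, Pmp22, Pmp2, Mag, Plp1, Sox2 and Ckm.

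Alternatives fixed before the data were examined were DESeq2 size factors (RLE), upper-quartile scaling, no low-count filter beyond 1 count, a CPM of at least 1 in 6 samples, title style as a covariate, each title style alone, Xist as a covariate, DESeq2 1.42.0 in place of edgeR, each library left out in turn, an estimated correlation for camera, and an adjusted p under 0.01 for the calls shared with the authors' deposited table. A fit without control 4 and cKO 4, a fit of the 8 libraries with Y-linked transcripts and 9 further gene lists were added after the values were seen. Genes named outside the rule were read from the same fits.

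The steps were tested on simulated data drawn from the control means and the library sizes and dispersions of all libraries, with 16694 genes tested. Far fewer genes were changed than were called in the data, so the recovery rates need not carry over. The test recovered 32.8% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 87.9% of those changed 4-fold, with 8 false calls among 131. Over 16689 simulated genes, the camera p-values were 3.17e-30 for a list of raised genes and 0.657 for a list of unchanged genes. Genes were simulated independently of each other, so these values do not test camera on lists of correlated genes.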

Results

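Polyadenylated RNA was sequenced from 12 samples of intact sciatic nerve of mice aged about 8 weeks, 6 from controls and 6 from conditional knockouts (cKO) of Bap1. Bap1 encodes a nuclear deubiquitinase that, with ASXL cofactors, removes ubiquitin from histone H2A. By the labels, all animals carried floxed Bap1 alleles, and the cKO animals also carried a Cre transgene under the promoter of Mpz, the gene of the main structural protein of Schwann cell myelin. Controls are labelled without Cre. The series' design text calls the 6 samples of each condition independent replicates. Totals ranged from 21461414 to 39554458 counts per library over 43432 annotated genes. The 4 libraries with number and letter titles, 2 per group, held 21461414 to 24550718 counts, and the 8 with Sp titles, 4 per group, held 31633250 to 39554458 counts.

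The first comparison was of Bap1 itself (ENSMUSG00000021901, GRCm38 chromosome 14, 31251450 to 31259944, plus strand), as a check of the genotype labels. Its level was 67.9 ± 2.06 CPM (counts scaled to library size, mean ± SD, n = 6) in control nerve and 59.8 ± 4.30 CPM (n = 6) in cKO nerve, or 88.1% of control. The log2 fold change was -0.18 (SE 0.056, edgeR adjusted p = 0.0272), and an exact two-sided permutation test of the group means of log2 CPM gave p = 0.00433, with 0.00216 as the smallest value the 924 arrangements allow. Single libraries spanned 65.0 to 69.8 CPM in controls and 55.2 to 65.6 CPM in cKO nerve. The call was lost without control 2, 3 or 4 or cKO 1, 2, 5 or 6 (adjusted p 0.0517 to 0.068), while the log2 fold change stayed between -0.21 and -0.16 over the leave-one-out fits. Within the Sp titles it was -0.14 (adjusted p = 0.238) and within the number and letter titles -0.23 (adjusted p = 0.237), and it was -0.18 with no low-count filter (adjusted p = 0.114). The count covers the whole gene, and the part removed by recombination was not given in the sources used here, so the level does not measure how complete the deletion was.

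Gene expression was then compared between cKO and control nerve. Of 16997 genes tested, 2076 were higher and 2591 were lower in cKO nerve, 4667 in all. Among them, 550 were more than 2-fold higher and 522 more than 2-fold lower, 1072 in all. The excess of lower genes depended on scaling, with 2154 higher and 2529 lower under RLE and 2343 and 2377 under upper-quartile scaling. Genes of myelin and sterol synthesis, including Mbp, Prx and Hmgcs1, were among those that fell, and genes of cell division and of repair Schwann cells, including Ccnd1, Shh and Gdnf, among those that rose. The first principal component of log2 CPM held 31.1% of the variance and parted the 6 cKO libraries (scores from 24.6 to 50.6) from the 6 controls (-44.71 to -29.55). The second held 22.8% and parted the number and letter titles (27.2 to 40.8) from the Sp titles, with control 4 at -59.25 and cKO 4 at -66.83. Within the Sp titles 3627 genes were called, and within the number and letter titles 728. Among the 4667 genes, 100% of those tested kept their sign within the Sp titles and 99.7% within the others. These genes were called in the fit of all 12 libraries, which holds both subsets, so the shared signs are not independent of it. A test by edgeR found 0 genes whose genotype effect differed between title styles at adjusted p under 0.05, with 934 at an unadjusted p under 0.05. Among the 8 libraries with Y-linked transcripts, 2364 genes were called.

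**Figure D1:**
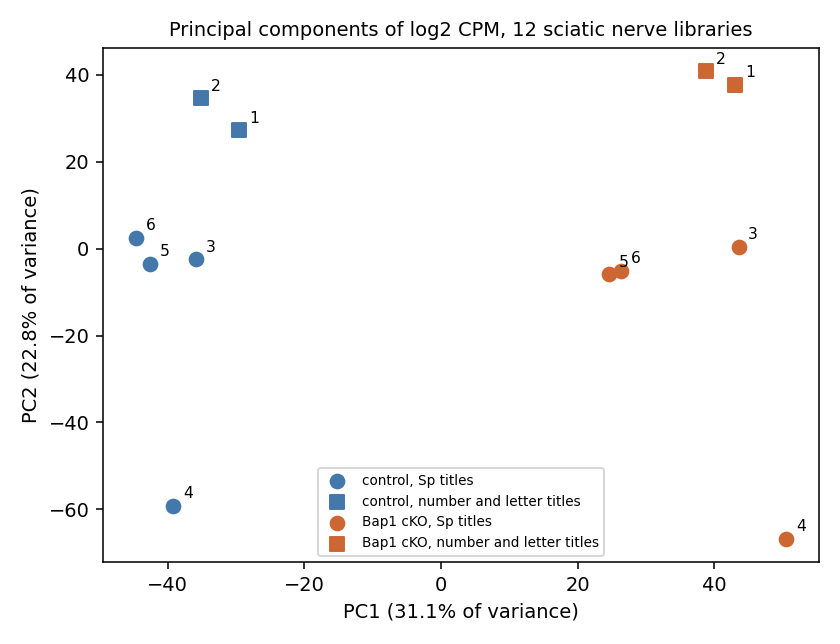
Principal component scores of the 12 libraries from log2 CPM of the 16997 genes tested. The x axis is PC1 (31.1% of variance) and the y axis PC2 (22.8%), with colour for the group, marker shape for the title style and a number for the replicate, and the 6 cKO libraries lie at 24.59 or more on PC1 and the 6 controls at -29.55 or less.

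The largest rises were in genes with low levels in control nerve. Tyrp1, an enzyme of melanin synthesis (chromosome 4, 80834123 to 80851719), rose from 0.773 ± 0.219 to 83.5 ± 54.9 CPM (n = 6 per group), a log2 fold change of 6.77 (SE 0.53, edgeR adjusted p = 3.46e-06). Pmel, which forms the fibrils of melanosomes, rose by 3.95 log2 units from 3.01 ± 0.652 to 46.6 ± 25.7 CPM. Crlf1, a secreted partner of the cytokine Clcf1, rose from 2.73 ± 0.831 to 68.4 ± 19.0 CPM (log2 fold change 4.645). Myrf, a transcription factor of oligodendrocyte myelin genes, rose from 2.41 ± 0.830 to 39.7 ± 8.99 CPM, and the oligodendrocyte homeodomain factor Nkx6-2 from 0.183 ± 0.143 to 4.44 ± 1.14 CPM. The other genes among the 10 largest rises were Shh, Adamdec1, Slc17a8, Clca3a2 and Chrm4, with log2 fold changes between 3.89 (Chrm4) and 4.19 (Shh). Clca3a2 belongs to a cluster of near-identical copies, so its level is uncertain. Of the exonic bases of Shh, 28.3% lie in exons of 9530036O11Rik on the other strand, and of those of Nkx6-2, 12.9% lie in exons of Inpp5a on the other strand. Whether counting used strand was not given in the sources used here.

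The largest falls took their genes to 1.27 CPM or less in cKO nerve. Slc6a15, a neutral amino acid transporter (chromosome 10, 103367783 to 103419377), fell from 41.9 ± 5.93 to 0.887 ± 0.466 CPM (n = 6 per group), a log2 fold change of -5.60 (SE 0.30, edgeR adjusted p = 1.32e-07). The neuregulin receptor Erbb4 fell from 19.7 ± 5.07 to 1.27 ± 0.352 CPM (-3.95), and the axoglial adhesion molecule Cntn1 from 22.0 ± 3.57 to 0.953 ± 0.439 CPM (-4.53). Jakmip2 (-4.53), Spock3 (-5.04), Csrnp3 (-4.79), Npy6r (-4.14) and the synaptic adhesion gene Il1rapl1 (-4.095) fell as well, as did Cyp2j13 (-4.71), whose level is uncertain because it lies in a cluster of similar copies. Sv2c, a synaptic vesicle glycoprotein gene, had the lowest log2 fold change, -6.20 (SE 1.21, adjusted p = 0.00293). Its control libraries fell into separate ranges, with 1.06, 1.32 and 1.01 CPM in controls 1, 2 and 5 and 27.9, 38.6 and 36.8 CPM in controls 3, 4 and 6, against 0.125 to 0.418 CPM in cKO nerve. Within the number and letter titles its log2 fold change was -2.57 and the call was lost (adjusted p = 0.0521).

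**Figure D2:**
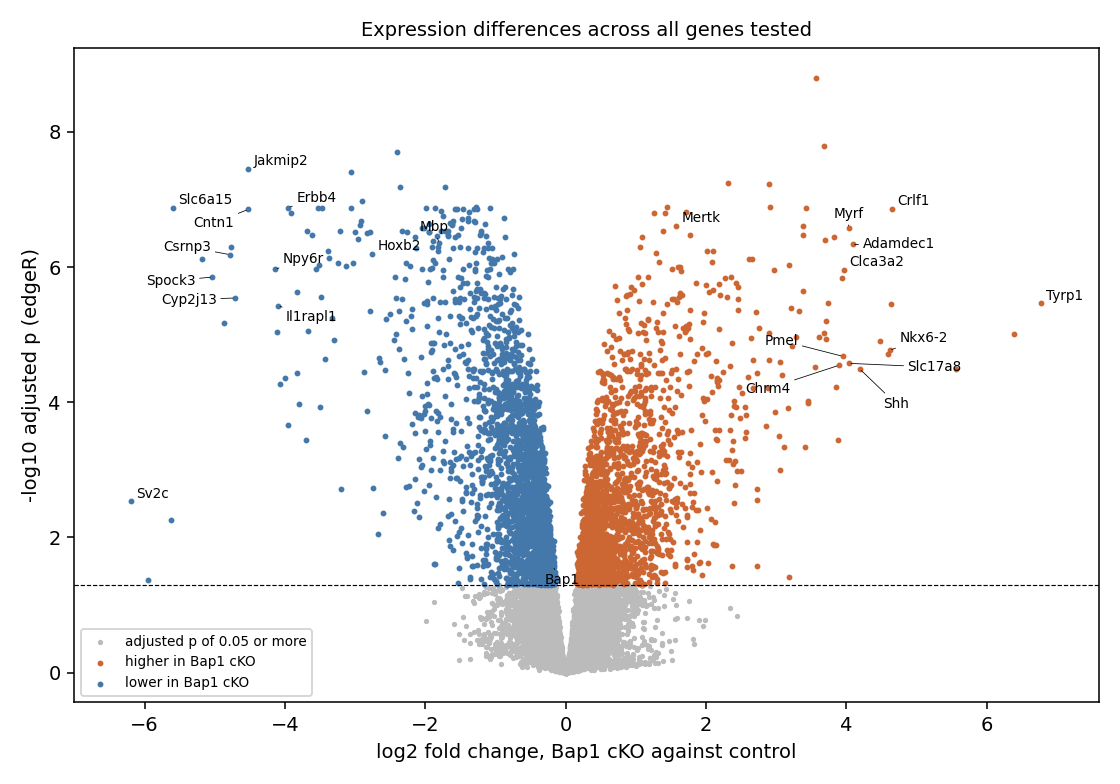
Log2 fold change of cKO against control (x axis) and -log10 of the edgeR adjusted p (y axis) for the 16997 genes tested, each a point. The dashed line marks an adjusted p of 0.05, above which 2076 genes (orange) were higher and 2591 (blue) lower in cKO nerve, from -6.20 for Sv2c to 6.77 for Tyrp1.

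Genes fixed as lists before the data were examined were then compared. Myelin genes moved in both directions: of 19 myelin structure genes, 7 fell, 3 rose and 9 did not pass. Mbp, the myelin basic protein gene (chromosome 18, 82475146 to 82585637), fell from 24580 ± 2676 to 7039 ± 1331 CPM (log2 fold change -1.80, SE 0.13, edgeR adjusted p = 4.43e-07, n = 6 per group). The myelin genes Ncmap (-1.28), Drp2 (-1.19), Prx (-0.95), Cnp (-0.77) and Pmp22 (-0.76) also fell, while Pmp2 (0.68), Mag (0.45) and Plp1 (0.40) rose. Mag did not pass without control 5 or 6 or cKO 3 or 4 (adjusted p 0.0503 to 0.0694), nor Plp1 without control 1, 3, 4, 5 or 6 or cKO 1 or 2 (adjusted p 0.0574 to 0.0872). Mpz, the most abundant of them, was at 55930 ± 13540 CPM in control and 42420 ± 10640 CPM in cKO nerve and did not pass (-0.40, adjusted p = 0.163). Control 1 was at 29589 CPM of Mpz against 54330 to 65585 CPM in the other controls, and without it Mpz passed (-0.53, adjusted p = 0.0178). Adjusted over the list alone, 8 fell and 3 rose. The list ranked below other genes (camera adjusted p = 0.0254), but not with the correlation of its genes estimated (adjusted p = 0.818 with an estimated correlation). The camera call was also lost without cKO 2 (adjusted p = 0.0531) or cKO 5 (adjusted p = 0.0557), and among the libraries with Y-linked transcripts (adjusted p = 0.053), where 5 fell and 0 rose by edgeR, or 6 and 1 adjusted over the list alone.

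Most genes of the lipid synthesis lists fell. Of 23 cholesterol synthesis genes 19 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -0.69. Hmgcs1, which makes the HMG-CoA of the mevalonate route, fell from 2575 ± 217 to 1106 ± 168 CPM (-1.22, SE 0.11, n = 6 per group), the rate-limiting Hmgcr by 1.02 log2 units, and Pmvk and Cyp51 each by 0.91. Of the exonic bases of Hmgcs1, 12.1% lie in exons of Gm48342 on the other strand. Of 20 genes of fatty acid and myelin lipid synthesis 13 fell and 2 rose (14 and 3 adjusted over the list alone). Ugt8a, which makes the myelin lipid galactosylceramide, fell from 1966 ± 290 to 877 ± 126 CPM (-1.17), and Fads2 (-0.997), Acly (-0.86) and Elovl6 (-0.77) fell too. Srebf1 (0.39) and Agpat4 (0.37) were the pair that rose, named after their values were seen, and Agpat4 did not pass without control 6 (adjusted p = 0.0528). Camera gave adjusted p = 3.1e-12 for the cholesterol list and 0.000566 for the fatty acid list, and both calls were lost with the correlation estimated (adjusted p = 0.354 and adjusted p = 0.466 with an estimated correlation).

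Genes of immature and repair Schwann cells rose, with 15 of 24 measured members higher, 2 lower and 7 not past the test (18 higher and 2 lower adjusted over the list alone). The phagocytic receptor Megf10 rose from 20.8 ± 3.02 to 65.1 ± 13.0 CPM (log2 fold change 1.65, SE 0.14, n = 6 per group), Runx2 by 1.62 and Egr3 by 1.88 log2 units, and Jun, the main transcription factor of the repair state, from 41.4 ± 5.76 to 67.5 ± 8.90 CPM (0.70). Cdh2 (-0.87) and Gap43 (-0.77) fell, and Jun and Gap43 were named after their values were seen. Within the Sp titles Gap43 did not pass (adjusted p = 0.0837). Of 10 genes listed as nerve injury genes under Polycomb, 8 were measured, of which 7 rose and 0 fell (7 and 0 adjusted over the list alone). Whether Polycomb repressed them in control nerve was not tested, and Igf2bp2 was at 27.1 CPM there. Gdnf, near 0 in control nerve, could pass the count filter only through its cKO level, so for such genes the filter favours rises. The morphogen Shh (chromosome 5, 28456815 to 28467256) rose from 1.20 ± 0.696 to 22.2 ± 11.5 CPM (4.19, SE 0.46), the neurotrophic factor Gdnf (chromosome 15, 7810846 to 7837575) from 0.160 ± 0.176 to 2.51 ± 0.744 CPM (3.86, SE 0.49) and Igf2bp2 by 0.85. Both lists ranked above other genes by camera (adjusted p = 1.41e-10 and 1.01e-07) and kept the call with the correlation estimated (adjusted p = 0.00756 and adjusted p = 0.0094 with an estimated correlation). Within the Sp titles neither did (adjusted p = 0.158 for each with an estimated correlation), nor did the nerve injury list among the libraries with Y-linked transcripts (adjusted p = 0.122 with an estimated correlation). As listed, they share Shh, Gdnf, Runx2, Olig1 and Bdnf, so their tests are not independent. Within the number and letter titles Shh (3.82, adjusted p = 0.0515) and Gdnf (4.79, adjusted p = 0.0539) did not pass.

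Among 19 regulators of Schwann cell myelination, 4 rose, 3 fell and 12 did not pass, with the same counts adjusted over the list alone. The adhesion receptor Adgrg6, which is needed to start myelination, fell from 146 ± 21.9 to 61.0 ± 8.76 CPM (-1.26, SE 0.12, n = 6 per group) and Nab1 by 0.81 log2 units, while Pou3f1, a factor of promyelinating cells, rose from 41.2 ± 8.53 to 167 ± 65.1 CPM (2.02, SE 0.25) and Nrg1 from 0.766 ± 0.278 to 4.13 ± 1.77 CPM (2.43, SE 0.34). Sox10 (-0.09, adjusted p = 0.558) and Egr2 (0.07, adjusted p = 0.887), named after their values were seen, did not pass. Of 10 Remak Schwann cell genes, 3 rose (L1cam 0.71, Chl1 0.54, Sox2 0.58) and 2 fell (Cdh2 -0.87, Scn7a -0.56), or 5 and 2 adjusted over the list alone. Sox2 did not pass within the Sp titles (adjusted p = 0.165). Of 14 nodal, axoglial and ion channel genes, 4 rose and 5 fell (6 and 5 adjusted over the list alone), among them the potassium channel Kcnj10 (2.56, SE 0.33), Ezr (0.72) and Nrcam (0.52), which rose, and Cntn1, which fell. The median log2 fold change of that list was 0.07, while its mean was -0.15. Camera gave adjusted p = 0.926, 0.584 and 0.956 for these lists in turn.

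Most cell cycle genes rose. Of 34 members 30 rose, 0 fell and 4 did not pass (32 and 0 adjusted over the list alone), with a median log2 fold change of 0.95. The G1 cyclin gene Ccnd1 rose from 114 ± 14.3 to 258 ± 28.4 CPM (1.175, SE 0.10, n = 6 per group), the spindle gene Tpx2 from 3.38 ± 0.713 to 7.86 ± 1.36 CPM (1.215), the ribonucleotide reductase gene Rrm2 by 1.55 and the replication licensing gene Mcm6 by 0.65 log2 units. Of the exonic bases of Ccnd1, 23.4% lie in exons of LTO1 on the other strand. Camera gave adjusted p = 4.28e-16, lost with the correlation estimated (adjusted p = 0.219 with an estimated correlation). Of 23 CDK inhibitor and p53 response genes, 10 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.0101, adjusted p = 0.154 with an estimated correlation). Bbc3 (0.67) and Trp53 (0.44) rose, and the CDK inhibitor gene Cdkn1b fell from 417 ± 39.1 to 300.1 ± 43.0 CPM (-0.48). Of 14 immediate early genes, 8 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000709, adjusted p = 0.354 with an estimated correlation). Fos rose from 14.7 ± 3.14 to 45.2 ± 7.32 CPM (1.62, SE 0.15), Egr1 by 1.05 and Nr4a1 by 0.72 log2 units.

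**Figure D3:**
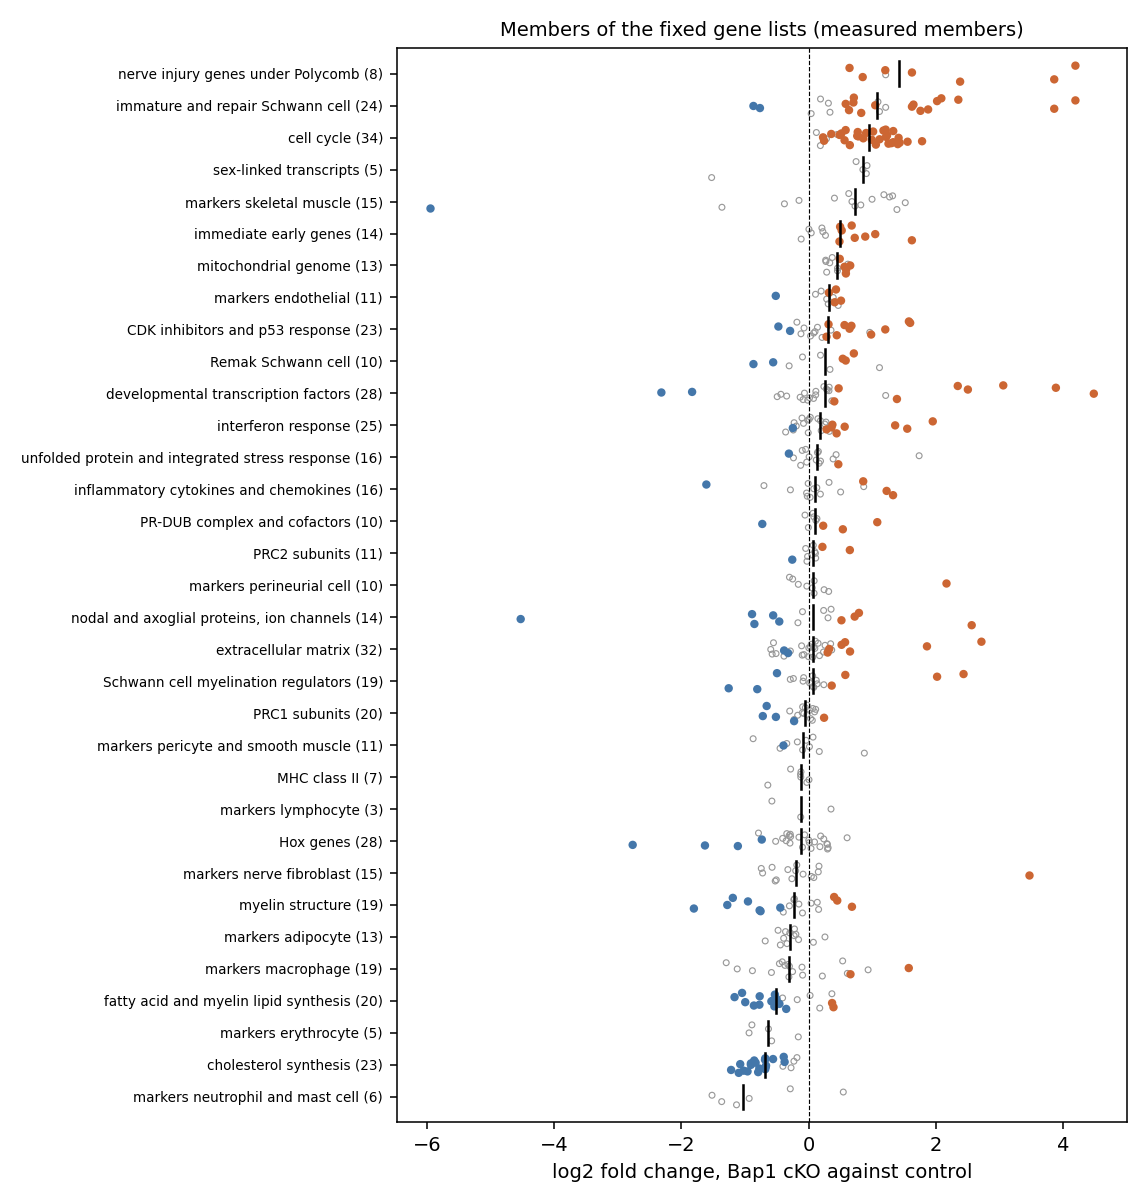
Log2 fold change of cKO against control (x axis) for the measured members of the 33 gene lists (y axis, number of measured members in brackets), each a point, with the list median as a black bar and points past an adjusted p of 0.05 filled, orange if higher and blue if lower in cKO nerve. All 30 cell cycle genes past the test lie right of 0 and all 19 cholesterol synthesis genes past it lie left.

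Genes of the BAP1 complex and of the Polycomb complexes PRC1 and PRC2 moved in both directions. Of all genes tested 27.5% were called, and whether the share in these lists differs from that was not tested. Of 10 genes of the BAP1 deubiquitinase complex, 3 rose and 1 fell. Asxl3 from 20.99 ± 4.59 to 44.3 ± 3.90 CPM (1.08, SE 0.14, n = 6 per group) and Mbd6 (0.54) were among those that rose, and Kdm1b fell from 38.4 ± 3.15 to 23.2 ± 1.42 CPM (-0.73, SE 0.07). Of 20 PRC1 subunit genes, 1 rose and 4 fell, with Phc1 (-0.66) and Cbx6 (-0.515) among those that fell. Of 11 PRC2 subunit genes, 2 rose and 1 fell, and Ezh2, a catalytic subunit, rose from 14.9 ± 1.68 to 23.4 ± 2.33 CPM (0.65). Camera gave adjusted p = 0.457, 0.322 and 0.548 for these lists in turn, and each count was the same adjusted over the list alone.

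Developmental transcription factors that are typical Polycomb targets moved in both directions. Of 69 genes listed, 28 were measured. Of these, 8 rose, 2 fell and 18 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.132 with an estimated correlation). A gene near 0 in control nerve, such as Barhl1 or Isl2, passes the count filter only if its cKO level is higher. Among such genes only rises can be counted, so the counts and the camera rank may lean towards rises. Tbx2 rose from 22.1 ± 2.04 to 57.9 ± 7.41 CPM (1.39, SE 0.09, n = 6 per group), and Barhl1 (0.065 ± 0.079 to 1.615 ± 0.5205 CPM) and Isl2 (0.086 ± 0.052 to 0.779 ± 0.083 CPM) rose from low levels, while Dlx2 fell from 1.70 ± 0.476 to 0.473 ± 0.182 CPM (-1.83). Of 28 Hox genes, 0 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.219). These were Hoxb2, which fell from 3.69 ± 0.632 to 0.540 ± 0.159 CPM (-2.77, SE 0.21), Hoxb3 (-1.63), Hoxb4 (-1.11) and Hoxd8 (-0.74). Hoxd8 did not pass within the Sp titles (adjusted p = 0.0569) or among the libraries with Y-linked transcripts (adjusted p = 0.158). Within the number and letter titles Hoxb3, Hoxb4 and Hoxd8 did not pass (adjusted p 0.0516 to 0.0959). Of the exonic bases of Hoxb2 and Hoxb3, 27.3% and 52.9% lie in exons of Hoxb3os on the other strand.

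Of 25 interferon response genes, 8 rose and 1 fell, with Cxcl10 (1.95), Zbp1 (1.36) and Mx1 (1.55) among the rises (camera adjusted p = 0.0498, adjusted p = 0.818 with an estimated correlation). That camera call was lost without control 1, 2, 3, 4 or 5 or cKO 2, 3, 4 or 5 (adjusted p 0.0534 to 0.135), without control 4 and cKO 4 (adjusted p = 0.0818), within the Sp titles (adjusted p = 0.264), and with RLE scaling or title style or Xist as a covariate (adjusted p 0.0505 to 0.0537). Among the libraries with Y-linked transcripts 8 rose and 0 fell, and the camera call was kept (adjusted p = 0.000645, adjusted p = 0.222 with an estimated correlation). Of 16 inflammatory cytokine and chemokine genes, 3 rose and 1 fell. The macrophage growth factor gene Il34 rose from 91.6 ± 13.3 to 166 ± 18.1 CPM (0.86, n = 6 per group), Ccl2 rose by 1.33 log2 units, and Spp1 fell from 757 ± 81.1 to 248 ± 103 CPM (-1.61). Ccl2 did not pass within the Sp titles (1.581, adjusted p = 0.0626) or the number and letter titles (0.784, adjusted p = 0.287). Of the exonic bases of Spp1, 18.8% lie in exons of Gm42793 on the same strand. Of 7 MHC class II genes, 0 rose and 0 fell by edgeR, with 1 at an unadjusted p under 0.05. Of 32 extracellular matrix genes, 7 rose and 2 fell, with Tnc (14.7 ± 3.23 to 53.4 ± 10.2 CPM, 1.86) and Timp1 (2.49 ± 0.860 to 16.3 ± 5.82 CPM, 2.715) the largest rises. That list passed camera without control 1 (adjusted p = 0.0395) or cKO 4 (adjusted p = 0.0262) though not with all libraries (adjusted p = 0.928 with an estimated correlation). Of 16 genes of the unfolded protein and integrated stress response, 1 rose (Ddit3 0.47) and 1 fell (Phgdh -0.31), and without control 4 and cKO 4 Phgdh did not pass (adjusted p = 0.0791). Camera gave adjusted p = 0.373, 0.926, 0.179 and 0.584 for the last 4 lists in turn, and these 5 lists had the same counts adjusted over the list alone. Of 13 genes of the mitochondrial genome, 5 rose and 0 fell (9 and 0 adjusted over the list alone), including mt-Nd1 from 2507 ± 284 to 3759 ± 1132 CPM (0.585; camera adjusted p = 0.00931, adjusted p = 0.818 with an estimated correlation). Within the Sp titles and among the libraries with Y-linked transcripts, 0 of these 13 passed by edgeR, also adjusted over the list alone. Their median log2 fold changes there were 0.435 and 0.539, and mt-Nd1 had adjusted p = 0.1 and 0.0629. Mitochondrial genes took 2.06% to 2.69% of counts in controls and 2.81% to 4.90% in cKO nerve, with 4.90% in cKO 4.

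Apart from endothelial markers, markers of the other cell types of nerve changed in few cases, where 27.5% of all genes tested were called. Of 19 macrophage markers, 2 rose and 0 fell (1 and 0 adjusted over the list alone), led by the phagocytic receptor Mertk, which rose from 63.5 ± 6.59 to 189 ± 27.2 CPM (1.57, SE 0.10, n = 6 per group). The median log2 fold change of that list was -0.30 and its mean -0.11, while camera ranked it upwards (adjusted p = 0.731). With title style as a covariate, 4 macrophage markers rose and 1 fell (2 and 0 adjusted over the list alone). Ms4a7 (1.019, adjusted p = 0.0344) was among those rises, and Gpnmb (-0.481, adjusted p = 0.046) fell. By edgeR with genotype alone, of 15 nerve fibroblast markers only Wif1 passed (0.180 ± 0.032 to 1.98 ± 1.38 CPM), of 10 perineurial markers only Crabp2 (7.24 ± 2.92 to 32.2 ± 8.95 CPM), and both rose. With title style as a covariate, the fibroblast markers Abca9 (-0.671, adjusted p = 0.0344) and Etv1 (-0.201, adjusted p = 0.047) passed too. DESeq2 also called Abca9 (-0.719, adjusted p = 0.0222). Of 11 pericyte and smooth muscle markers only Pdgfrb passed, and it fell by 0.41 log2 units, though not without control 4 and cKO 4 (adjusted p = 0.107). Nor did Pdgfrb pass within the Sp titles (adjusted p = 0.114), the number and letter titles (0.0972) or the libraries with Y-linked transcripts (0.125). Of 11 endothelial markers, 4 rose, among them Emcn (0.51) and Esam (0.43), and Kdr fell (-0.52), or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0498, adjusted p = 0.818 with an estimated correlation). Its camera call was lost without control 2, 4 or 5 or cKO 1, 4, 5 or 6 (adjusted p 0.0512 to 0.114), without control 4 and cKO 4 (adjusted p = 0.0818), among the libraries with Y-linked transcripts (adjusted p = 0.266), within the Sp titles (adjusted p = 0.06), and with RLE scaling or title style as a covariate (adjusted p 0.0505 to 0.0514). None of the 3 lymphocyte, 6 neutrophil and mast cell, 13 adipocyte and 5 erythrocyte markers measured passed by edgeR, and 0 were at an unadjusted p under 0.05. Camera gave adjusted p = 0.949 for fibroblast, lymphocyte, neutrophil and mast cell, erythrocyte and skeletal muscle markers, 0.457 for perineurial, 0.846 for pericyte and 0.464 for adipocyte markers, which within the Sp titles ranked lower (adjusted p = 0.0415, adjusted p = 0.917 with an estimated correlation).

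Libraries differed in skeletal muscle transcripts and in sex. Ckm, the muscle creatine kinase gene, was at 1469 CPM in control 4 and 3036 CPM in cKO 4, against 0.383 to 82.8 CPM in the other libraries. Of 15 skeletal muscle markers, only Myh2 passed over all genes and none adjusted over the list alone. Myh2 was at 214 CPM in control 4 and at most 1.40 CPM elsewhere, and without control 4 its log2 fold change went from -5.95 to -0.67 (adjusted p = 0.286). Its call was also lost without any 1 of the 6 cKO libraries (adjusted p 0.069 to 0.0841). Ddx3y, a Y-linked gene, was at 97.8 CPM or more in 3 controls and 5 cKO libraries and at most 0.266 CPM in 3 controls and 1 cKO library. None of the 5 sex-linked transcripts listed passed between the genotypes (camera adjusted p = 0.564). Without control 4 and cKO 4, 3813 genes were called between the genotypes.

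**Figure D4:**
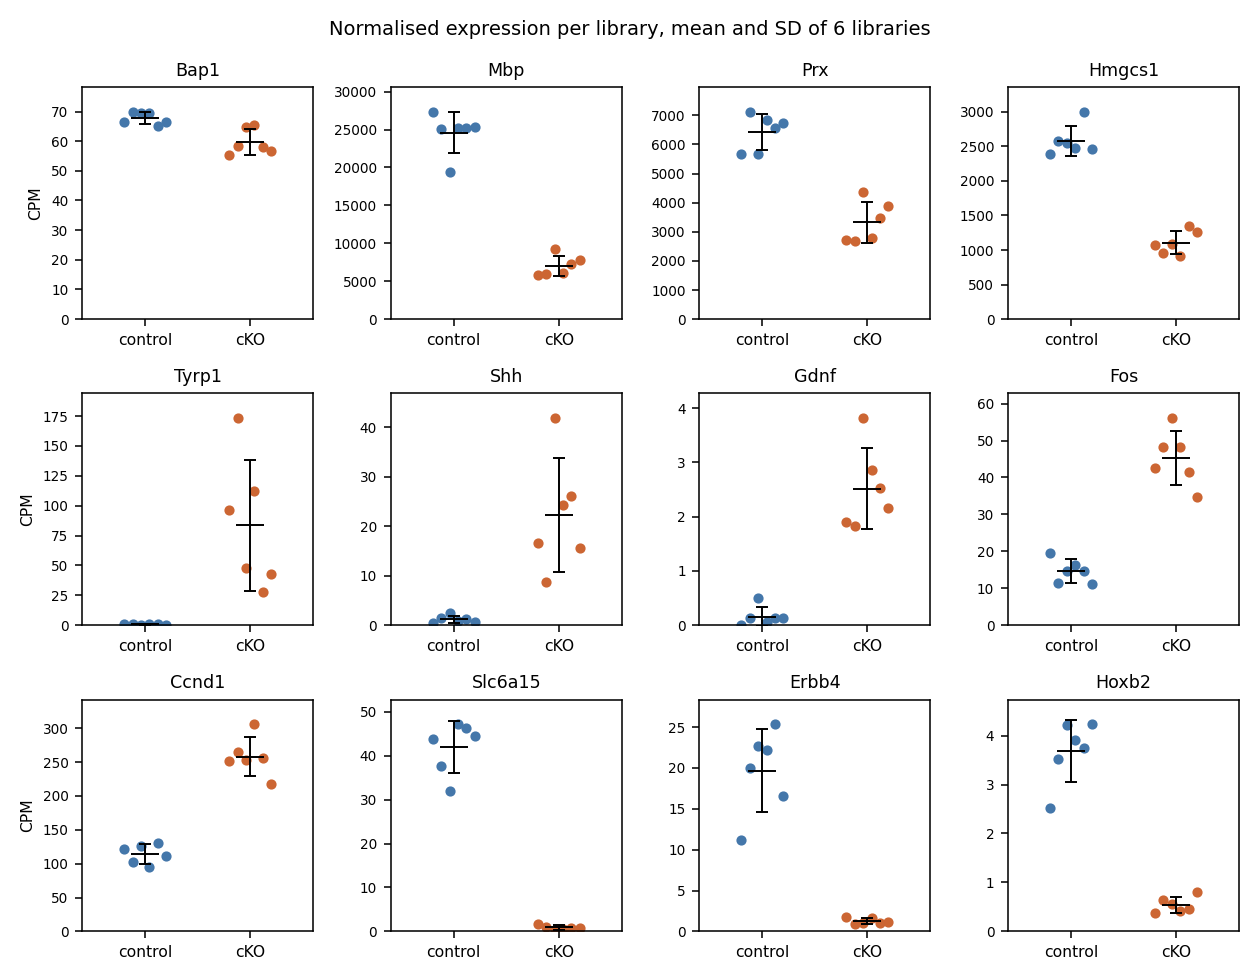
Expression in CPM (y axis, linear from 0, own scale per panel) of 12 genes in the 6 control and 6 cKO libraries. Points are libraries, with the mean as a horizontal bar and the SD as the error bar, and apart from Bap1, where cKO libraries reach 65.6 CPM and the lowest control is at 65.0 CPM, the groups do not overlap in any panel. Tyrp1, Shh, Slc6a15 and Erbb4 were named by a rule that requires no overlap. The other genes apart from Bap1 were named for a small adjusted p, so the lack of overlap follows in part from the choice.

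The calls were last compared with the authors' deposited table of a DESeq2 fit, as a description of how far both tables list the same genes. The authors' deposited table lists 5250 genes, 2455 with a positive and 2795 with a negative log2 fold change, and an adjusted p of at most 0.0498. Of 4964 genes found by symbol in both tables, 4964 had the same sign when its direction was read as cKO against control, and 4585 were called in both. For Bap1 the authors' deposited table gives a log2 fold change of -0.18 (adjusted p = 0.0228), for Mbp -1.80, for Tyrp1 6.76 and for Slc6a15 -5.61. DESeq2 rerun on the counts with genotype alone called 5250 genes, 2455 higher and 2795 lower. At an adjusted p under 0.01 in both tables, 2897 genes were shared.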

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

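The spread test took the highest or lowest library of a group, and a library stood apart where its gap to the nearest of the others, divided by the range of the group, both on log2 CPM, was above 0.625. Levels below are in CPM. Of 300 groups of 6 libraries tested over the named genes, 26 held such a library, and 15 would by chance. The genes of one list are correlated, so these are not independent.

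Control 1 stood apart in 9 genes. Its level was low in Asxl3 (gap ratio 0.727, 12.1 CPM against 19.8 to 23.9 in the other controls), Hoxb2 (0.647), Igf2bp2 (0.652), Elovl6 (0.647), Adgrg6 (0.738, 103 CPM against 145.7 to 164.9) and Col4a2 (0.73). It was high in Ier2 (0.643) and in the MHC class II genes H2-Ab1 (0.656, 125 CPM against 27.6 to 46.5) and H2-Aa (0.672).

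Control 5 was high in the red cell genes Hbb-bs (gap ratio 0.786, 309 CPM against 16.1 to 30.3), Hbb-bt (0.769), Hba-a1 (0.748) and Alas2 (0.745), and in Hmgcs1 (0.661). The haemoglobin genes are near-identical copies, so their single levels are uncertain. In control 4, Myh2 was high (0.799, 214 CPM against 0.353 to 1.40) and Chrm4 was low (0.722, 0 CPM against 0.176 to 0.335). Control 3 was low in Mbp (0.755, 19400 CPM against 25110 to 27290) and high in Emcn (0.644), and control 2 was high in Ncmap (0.681).

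In cKO nerve, replicate 6 was low in the Y-linked genes Uty (gap ratio 0.935), Kdm5d (0.942) and Eif2s3y (0.889), and in Aif1 (0.655). Replicate 4 was low in Bbc3 (0.646) and Cd79b (0.759), and replicate 3 was high in Dlx2 (0.709).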

How the results depend on the processing

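The fits of the 8 libraries with Y-linked transcripts and without control 4 and cKO 4 were chosen after the values were seen. The number of genes changed stayed within 1.5 times 4667 under both other scalings, both other filters, either covariate, DESeq2 (5250), the Sp titles (3627), without control 4 and cKO 4 (3813), and without each library in turn (3991 to 4932). Within the number and letter titles, 2 libraries per group, it was 728 (297 higher, 431 lower), of which 512 were changed more than 2-fold (233 higher, 279 lower). Among the libraries with Y-linked transcripts it was 2364 (1078 higher, 1286 lower). Both fits hold fewer samples. The Bap1 log2 fold change kept its sign in all settings and lost its call with no low-count filter (-0.178), in the Sp titles (-0.136), in the number and letter titles (-0.225), without control 4 and cKO 4 (-0.167) and in the libraries with Y-linked transcripts (-0.157). Without each library in turn it ranged from -0.208 to -0.16, and the cause was not tested. With an estimated correlation, 2 of the fixed lists passed. At an adjusted p under 0.01, 2897 calls were shared with the authors' deposited table. Of 149 other named genes, Myh2 reversed, to 0.018 within the number and letter titles, where 62 lost the call. In the Sp titles 19 lost it, and in the libraries with Y-linked transcripts 18. When single libraries were left out, 10 lost it at least once (Aif1, Asxl2, Ccl3, Eed, Egfl7, Myh2, Rnf2, mt-Atp6, mt-Co2 and mt-Co3) and 7 gained it. Xist as a covariate was not run for Xist itself. No paired analysis was possible because the replicate numbers follow the order of deposit.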

Other observations

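The lists in this part, and the tests of melanocytes and of a smaller share of Schwann cells, were chosen after the values were seen. Genes that prompted a family list are members of it, so the family counts and camera tests are not independent evidence. Of 8 genes of the GDNF family and its receptors measured, 4 rose and 1 fell. The artemin receptor Gfra3 rose from 5.80 ± 1.604 to 49.0 ± 24.4 CPM (mean ± SD, n = 6 per group; log2 fold change 3.08, SE 0.34), Gdnf rose by 3.86 and Gfra2 fell by 0.52 log2 units, though not past the test without control 4 and cKO 4 (adjusted p = 0.0806; for the list, camera adjusted p = 0.0301, adjusted p = 0.148 with an estimated correlation). Of 10 genes of the CNTF and LIF family, 5 rose and 1 fell (camera adjusted p = 0.00235, adjusted p = 0.148 with an estimated correlation). Clcf1, the partner of Crlf1, rose from 5.11 ± 1.16 to 21.6 ± 3.98 CPM (2.08), and Osmr (0.63) and Socs3 (0.69) rose while Il6ra fell by 0.56 log2 units, a call lost without control 3, 4 or 5 or cKO 1, 2, 3, 4 or 5 (adjusted p 0.0509 to 0.0778).

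Of 12 ErbB ligand and receptor genes, 2 rose, Btc (2.35) and Nrg1 (2.43), and Erbb4 fell by 3.95 log2 units (camera adjusted p = 0.671). The 3 anterior Hoxb genes measured all fell, as given among the Hox genes. Of 5 posterior Hoxb genes, 0 passed by edgeR and 0 were at an unadjusted p under 0.05 (camera adjusted p = 0.671), with Hoxb7 at 2.91 ± 0.376 CPM in control and 3.60 ± 0.630 CPM in cKO nerve. Whether these groups differ from each other was not tested.

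The number of genes changed was set against other explanations. Of 100 drawn splits of the 12 libraries into 6 and 6, 1, the real one, gave as many as 4667 genes, with 2 as the highest other. Again only the real one gave as many as 1072 genes changed more than 2-fold, with 1 as the highest other. A share of 1 in 100 is the smallest the draw allows, so it argues against chance without excluding it. The other splits mix the genotypes, and factors that go with genotype are not covered. Uneven sexes and skeletal muscle as the main cause were argued against by fold changes that held, with a median ratio to the full fit of 0.981 among the libraries with Y-linked transcripts (lower quartile 0.891) and 0.961 without control 4 and cKO 4 (lower quartile 0.892). The genes were called in the full fit, which shares the libraries of both subsets, so the ratios are not independent of it. Each group held 1 library rich in muscle transcripts, so the ratio for muscle is a weak test. After trends on exonic length and GC content were taken out, 93.4% of the 1068 genes changed more than 2-fold that had both values were still beyond it. The Cre transgene and the loss of Bap1 cannot be told apart, since 0 controls carried Cre by the labels.

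The rise of Tyrp1 and Pmel was set against melanocytes in the sample. In the 6 cKO libraries, counts of Dct or Mlana, abundant melanocyte transcripts, were at most 1.79% of those of Tyrp1, below an assumed bound of 10% for melanocytes, while Pmel was at 45.2% to 64.6%. Of 8 melanocyte genes measured, 4 rose and 1 fell (camera adjusted p = 0.0242, adjusted p = 0.216 with an estimated correlation), and 1 was at 10 CPM or more in control nerve. Uneven sexes were argued against by a Tyrp1 log2 fold change of 6.831 (SE 0.835) among the libraries with Y-linked transcripts. Dct itself rose from 0.2001 ± 0.0795 to 1.03 ± 0.504 CPM (2.32, adjusted p = 0.000714), as melanocytes would also bring, so a small share of them stays open, and which cells express Tyrp1 and Pmel was not tested.

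The fall of Mbp was set against a smaller share of Schwann cells. Of 24 Schwann cell lineage genes, 18 of them also in fixed lists, 4 rose and 3 fell (camera adjusted p = 0.891), and their quartiles of -0.251 and 0.176 lay above the Mbp log2 fold change plus 2 SE, -1.543, which argues against a smaller share as the whole cause. Of the exonic bases of Mbp, 0% lie in exons of another annotated gene. Whether Mbp fell within each Schwann cell was not tested.

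Because Myrf, Omg and Nkx6-2 were among the large rises, it was tested whether oligodendrocyte genes may have risen as a group. Without those 3 genes the list went the other way (limma camera, downwards, adjusted p = 0.0301, and 0.0162 before adjustment over the added lists). Of 29 measured, 7 rose and 13 fell, with Cldn11 at -3.04 and Mog at 1.73 (adjusted p = 0.151 with an estimated correlation), 8 were in fixed lists and 16 were at 10 CPM or more in control nerve. Among those that fell were Mbp (24580 CPM in control nerve), Ugt8a (1966 CPM) and Cnp (1904 CPM), while Plp1 (1519 CPM) and Mag (519.6 CPM) rose. These are also in the fixed myelin and lipid lists. The test therefore cannot tell oligodendrocyte genes from myelin genes of Schwann cells.

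Synaptic adhesion genes were tested for holding more calls than other genes. Without the genes that prompted the list, 9 rose and 10 fell of 49 measured, 38.8% against 27.5% of all genes tested (one-sided Fisher exact p = 0.0563), and camera gave adjusted p = 0.671. The median log2 fold change was 0.07 and the mean -0.16. By the bound of 0.05 set before the test, the hypothesis was not met. The reading was changed to open after the p was seen, because a p just above the bound does not show that the shares are alike. Slitrk1 (-2.56) and Lrrc4c (-2.28) fell and Adgrb2 rose by 1.61 log2 units.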
